A study of Mus musculus with 6 samples.

How the data were processed

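Kidneys of 6 mice, 3 per group, were each sequenced as 1 library on an Illumina NovaSeq X Plus, per the labels' protocols. The labels describe the groups as separate mice, so the spread between replicates is a spread between animals. The library kit is described only as compatible with Illumina, and whether it keeps the strand is not given in the sources used here, so a gene and an overlapping antisense gene cannot be told apart. Per the submitters' processing notes, FastQC, Trim Galore 0.6.6, STAR 2.7.9a and RSEM 1.3.3 were used with the genome build GRCm39. The annotation release is not given in the sources used here.

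The authors deposited 1 RSEM gene table per library, with expected counts, TPM and FPKM per gene, per the file headers. The deposited expected counts are not normalized. Of all listed genes, those without a count included, 10.4% to 11.1% held a value that was not whole. RSEM divides reads that fit several genes, which can leave such values. TPM was deposited by the authors as a length-scaled transcript share and was used here only in an alternative. In TPM the short Rn7s1 and Rn7s2 took 55.5% to 59.4% of a library, so TPM of the other genes depends on them. FPKM was deposited by the authors and was not used here.

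The tables list 57180 Ensembl gene IDs. Symbols came from a GENCODE vM21 annotation, which is on another genome build and was used for names and for the sequence content of transcripts only, so no coordinates are given. By gene ID 51884 were named, by transcript ID 247, and 5049 kept their ID. A gene without a name, ENSMUSG00002076161, took 1.78% to 2.39% of the counts. In all, 31462 genes had a count above 0 in a library.

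Expected counts were rounded to whole numbers. Genes were filtered with filterByExpr, scaled by TMM and tested with edgeR 4.0.16 (quasi-likelihood, glmQLFit and glmQLFTest, group as the only term) in R 4.3.3, and p values were adjusted by Benjamini and Hochberg with a threshold of 0.05. Standard errors are the log2 fold change divided by the root of the F statistic, and intervals are 95% intervals. CPM values are scaled by TMM. The interval reached a median of 0.281 log2 units to either side and the common biological coefficient of variation was 0.105. The 95% intervals include the estimated variation between mice as well as counting error. The reads carry no molecular identifiers.

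There were 38 gene lists fixed before the data were examined, 21 of pathways and 17 of cell types, and 34 had at least 3 measured genes. They were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 34 lists, and again with an estimated correlation and with fry. With an estimated correlation 0 lists passed, and with fry's test in 1 direction 0. A call lost with an estimated correlation does not by itself show correlated genes. The macrophage list lost its call at an estimate of -0.023, below the preset 0.01. Fry's mixed test, which asks for changes in either direction, called cell cycle (adjusted p = 0.00117), macrophage (0.00177), extracellular matrix and fibrosis (0.0142) and cholesterol synthesis (0.0230). Fits with libraries left out used the preset correlation alone. Members of a list were also counted adjusted over the list alone. Scores are the mean log2 CPM of a list's genes minus the vehicle mean.

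The genes named in the text followed a rule also fixed before the data were examined. It took up to 12 genes per direction among those past the threshold with groups that do not overlap, the 5 with the lowest p in each direction, the 4 members with the lowest p of each called list, the 2 with the lowest p of each other list, and a fixed set of genes of senescence, inflammation, injury, mitochondria and fibrosis. Unnamed genes, predicted genes and pseudogenes were left out of the first parts. Some genes that the rule takes from lists that did not pass are not described singly, and 1 gene that the rule takes is not reported here. Adipoq and other genes named beside the adipocyte transcripts are members of a fixed list that were below the filter.

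The edgeR step was tested on simulated counts for these 18092 genes, with 200 genes changed in each of 3 runs. For the comparison of nanoplastic with vehicle, 13.3% of genes changed by 1.25-fold, 64.0% by 1.5-fold, 74.7% by 2-fold and 92.0% by 3-fold were called, with 17.7 false calls on average per run. Over the 3 runs these were 20, 96, 112 and 138 of 150 genes each, so the share of false calls exceeded the nominal 0.05. The changed genes were drawn from those with a mean of at least 1 CPM, so the percentages do not hold for rarer transcripts. Of the unchanged genes 5.02% had an unadjusted p under 0.05. The list test with the preset correlation was tried in a separate run that shifted the matrix list alone by -0.25 in log2. It called 1 list, the shifted one. Counts were drawn independently for each gene, so that run cannot show how the preset correlation fares where genes correlate.

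Alternatives were RLE, upper-quartile and library size scaling, leaving out mitochondrial genes, no filter, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, robust dispersion, limma-trend on log2(TPM + 1) and log2(TPM + 0.1) for genes with a mean TPM of at least 0.5, counts without rounding, a replicate block, each library left out, an adjusted p threshold of 0.1 and a minimum log2 fold change of 1. The legacy form of the edgeR test and the fit without vehicle 3 and nanoplastic 1 were chosen after seeing the data. No libraries were duplicates, since every pair differed by at least 8.32 times the sampling noise in a chi-square per degree of freedom over genes with at least 50 counts. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.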

Results

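Total kidney RNA was sequenced from 6 male C57BL/6J mice, 3 given deionized water (vehicle, 0 mg/kg) and 3 given cationic polystyrene nanoparticles (nanoplastic, 200 mg/kg) by mouth once daily for 6 weeks. The mice were 7 weeks old when obtained. The deposited gene tables held 26292760, 23748774 and 23420454 expected counts for vehicle mice 1, 2 and 3, and 23585274, 23793640 and 19408534 for nanoplastic mice 1, 2 and 3. Between 25537 and 26578 genes had a count in a library. The nuclear protein-coding genes took 76.9% ± 0.6 (SD, n = 3) of the counts in vehicle and 76.9% ± 0.3 (SD, n = 3) in nanoplastic libraries. The 7SL RNA genes Rn7s1 and Rn7s2, which are near-identical copies, together took 11.5% ± 0.9 (SD, n = 3) and 11.5% ± 0.8 (SD, n = 3).

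The series title names mitochondrial dysfunction, inflammation and senescence in tubular epithelium, and the single comparison asked which kidney transcripts differed after nanoplastic. Transcripts of extracellular matrix, dividing cells, red blood cells and macrophages were lower in nanoplastic kidneys as groups in a set test with a preset correlation, a call that was lost in each with an estimated correlation (adjusted p between 0.459 and 0.811). The lists for inflammation, senescence and tubular injury did not pass. Col3a1, a fibrillar collagen, measured 80.2 ± 10.9 CPM in vehicle and 48.6 ± 3.52 CPM in nanoplastic mice (SD, n = 3 each; log2 fold change -0.72, SE 0.10). Col1a1, another fibrillar collagen, measured 26.6 ± 2.51 and 16.5 ± 1.37 CPM (SD, n = 3 each; log2 fold change -0.69, SE 0.10). Mki67, a marker of dividing cells, measured 11.6 ± 0.857 and 7.15 ± 0.279 CPM (SD, n = 3 each; log2 fold change -0.70, SE 0.11). Azgp1, which encodes a secreted zinc-binding glycoprotein, measured 87.3 ± 3.46 and 128.6 ± 12.4 CPM (SD, n = 3 each; log2 fold change 0.56, SE 0.08).

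No single gene passed the test over all genes. Of 18092 genes tested with edgeR's quasi-likelihood test, 0 had a Benjamini-Hochberg adjusted p under 0.05, and the lowest adjusted p was 0.156, shared by Col3a1, Azgp1 and Col1a1. At an unadjusted p under 0.05 there were 1342 genes, 688 higher and 654 lower, against 905 expected by chance, while the other 9 splits of the 6 libraries into 3 and 3 gave 387 to 1512. At that unadjusted level limma-voom on the same genes gave 1301. DESeq2, run without this count filter, gave 915 over a larger set of genes, since its own filtering by mean count acts on the adjusted p. The 915 is therefore not comparable with the 905 expected by chance among 18092 genes. After adjustment DESeq2 called 56 genes, 19 higher and 37 lower, and limma-voom called 0. The groups did not overlap in 2327 genes, or 12.9%, where chance gives 10% for 3 against 3. For 84.4% of genes the 95% confidence interval excluded a change of 2-fold in either direction. Removing nanoplastic 1 from the edgeR test gave 10 genes, 6 higher and 4 lower. Col1a1, Col3a1 and Azgp1 were among these 10. Removing vehicle 3 gave Col3a1 alone (adjusted p = 0.0387), and removing nanoplastic 3 gave Aqp4 alone (log2 fold change 1.29, adjusted p = 0.0124), which is named after its value was seen.

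**Figure D1:**
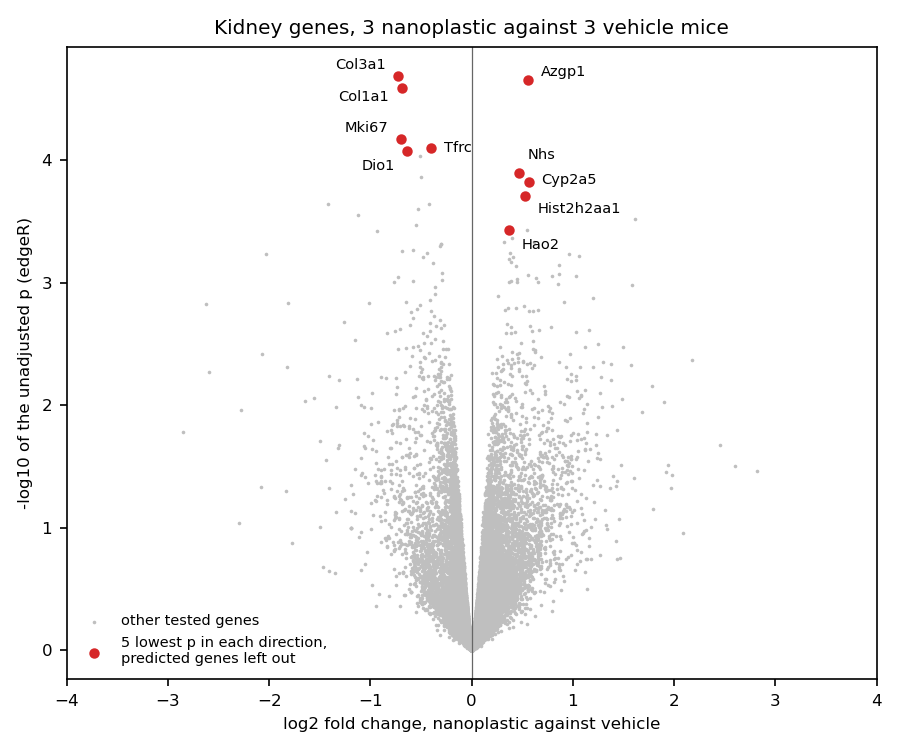
Each point is 1 of the 18092 tested kidney genes, with the log2 fold change of nanoplastic against vehicle on the x axis and -log10 of the unadjusted edgeR p on the y axis. Red points are the 5 genes with the lowest p in each direction once predicted genes, unnamed genes and pseudogenes are left out, led by Col3a1 at a log2 fold change of -0.72 and Azgp1 at 0.56, and 0 genes passed an adjusted p of 0.05.

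Predicted genes, unnamed genes and pseudogenes left out, the 5 genes with the lowest p in the higher direction were Azgp1, Nhs, Cyp2a5, Hist2h2aa1 and Hao2. The predicted gene Gm48627, named after its value was seen, had a lower p than Hao2. Nhs had a log2 fold change of 0.47 (SE 0.08). Cyp2a5, a cytochrome P450, measured 58.9 ± 4.81 and 87.2 ± 11.9 CPM (SD, n = 3 each). Hao2, a peroxisomal hydroxy acid oxidase, measured 197.4 ± 16.9 and 254.6 ± 4.60 CPM (SD, n = 3 each). Hist2h2aa1 is uncertain because it has a near-identical copy that can share its reads. In the lower direction the 5 genes were Col3a1, Col1a1, Mki67, Tfrc and Dio1. Tfrc, the transferrin receptor, measured 144.4 ± 9.07 and 109.6 ± 1.31 CPM (SD, n = 3 each). Dio1, a deiodinase acting on thyroid hormone, measured 20.2 ± 2.18 and 13.0 ± 0.893 CPM (SD, n = 3 each). In all 10 genes the libraries of the groups did not overlap, and their edgeR adjusted p lay between 0.156 and 0.311.

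The extracellular matrix and fibrosis list fell as a group by 0.25 in median log2 fold change, with 22 of 24 measured members negative and 2 positive (camera with a preset correlation, adjusted p = 2.19e-09). The call was lost with an estimated correlation, at an adjusted p of 0.582. Over all genes 0 members passed, and adjusted over the list alone 9 were lower. Besides the collagens, Fn1, which encodes fibronectin, measured 55.7 ± 4.68 and 41.0 ± 4.27 CPM (SD, n = 3 each). Sparc, a collagen-binding matrix protein, measured 79.5 ± 2.71 and 64.3 ± 1.93 CPM (SD, n = 3 each). The mean score of the list, in log2 units against the vehicle mean, was -0.100, -0.360 and -0.355 in nanoplastic mice 1, 2 and 3, and -0.102 in vehicle 3. Smooth muscle and mural cell markers, some of which are also in the matrix list, had a median of -0.06 over 8 genes (adjusted p = 0.354, and 0.0298 without nanoplastic 1).

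The cell cycle list fell by 0.35 in median log2 fold change, with 19 of 21 measured members negative (camera, adjusted p = 1.31e-06). With an estimated correlation the adjusted p was 0.539. Adjusted over the list alone 3 members were lower. Top2a, a DNA topoisomerase of dividing cells, measured 5.71 ± 0.317 and 3.86 ± 0.528 CPM (SD, n = 3 each). Rrm2, a subunit of ribonucleotide reductase, measured 3.27 ± 0.177 and 2.07 ± 0.273 CPM (SD, n = 3 each). Kif11, a mitotic kinesin, had a log2 fold change of -0.57 (SE 0.23). The scores of the 3 nanoplastic libraries were all below those of the 3 vehicle libraries.

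Macrophage markers were negative in 11 of 11 measured genes, with a median log2 fold change of -0.17 (camera, adjusted p = 0.000396). With an estimated correlation the adjusted p was 0.459, although the estimate, -0.023, was below the preset 0.01. Correlation among these genes therefore does not account for the lost call. Adjusted over the list alone 0 members were lower. Itgam, an integrin subunit of myeloid cells, measured 2.19 ± 0.160 and 1.44 ± 0.104 CPM (SD, n = 3 each). Adgre1, a macrophage surface receptor, had a log2 fold change of -0.35 (SE 0.15), C1qa of -0.19 (SE 0.10) and Lyz2 of -0.22 (SE 0.12).

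Erythrocyte markers were negative in 5 of 5 genes, with a median log2 fold change of -0.49 (camera, adjusted p = 0.000174). With an estimated correlation the adjusted p was 0.811, and adjusted over the list alone all 5 were lower. Hbb-bt, a beta globin gene, measured 60.5 ± 13.3 and 40.1 ± 3.92 CPM (SD, n = 3 each), and Alas2, the erythroid enzyme of heme synthesis, measured 16.2 ± 2.97 and 11.4 ± 0.784 CPM (SD, n = 3 each). Hba-a2 and Hbb-bs had log2 fold changes of -0.49 (SE 0.14) and -0.44 (SE 0.14). The globin genes are near-identical copies, so the division of reads among them is uncertain. Vehicle 3 had a score of -0.343, lower than the -0.297 of nanoplastic 1.

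**Figure D2:**
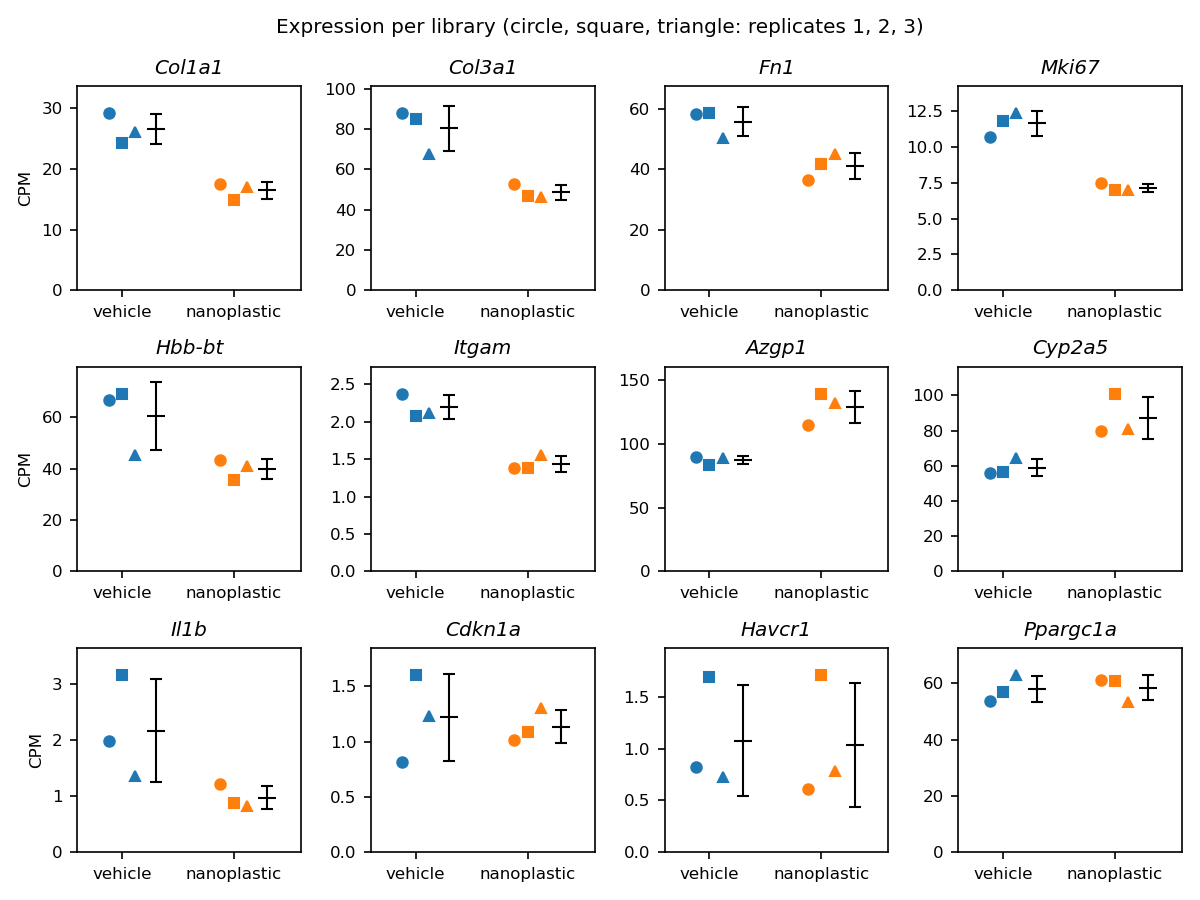
Normalised expression in CPM (counts scaled to the library size after TMM, y axis, from 0) of 12 genes in each library by group (x axis), with circles, squares and triangles for replicates 1, 2 and 3 and black bars for mean ± SD (n = 3). Col1a1 lay at 16.5 CPM on average in nanoplastic and 26.6 CPM in vehicle libraries without overlap, while the groups overlapped for Cdkn1a, Havcr1 and Ppargc1a.

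For mitochondria, the nuclear-encoded oxidative phosphorylation list fell by 0.09 in median log2 fold change, with 72 of 75 measured members negative (camera, adjusted p = 4.59e-08). With an estimated correlation, which was 0.685 among these genes, the adjusted p was 0.811. Adjusted over the list alone 0 members were lower. Uqcrq, Ndufa1, Ndufa8 and Atp5g3, subunits of respiratory complexes and ATP synthase, had log2 fold changes of -0.24 (SE 0.09), -0.18 (SE 0.08), -0.18 (SE 0.07) and -0.14 (SE 0.06). The score of vehicle 3 was -0.095, lower than the -0.081 and -0.024 of nanoplastic 2 and 3. The 13 mitochondrially encoded subunits had a median of -0.04 (adjusted p = 0.318). Of these mt-Co3 measured 957.5 ± 181 and 671.5 ± 33.0 CPM (SD, n = 3 each) and mt-Co2 103.0 ± 35.5 and 72.6 ± 8.55 CPM (SD, n = 3 each), with reads that can be shared with nuclear copies. Adjusted over the list alone 1 of the 13, mt-Co3, was lower. DESeq2 also called mt-Co3 lower (adjusted p = 0.00131), and edgeR did not (adjusted p = 0.394).

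Genes of mitochondrial fatty acid oxidation fell by 0.07 in median log2 fold change, with 13 of 17 negative (camera, adjusted p = 0.0335; adjusted p = 0.811 with an estimated correlation). The call was lost without nanoplastic 1 (adjusted p = 0.555), vehicle 1 (0.138) or vehicle 2 (0.0726), and with scaling by library size alone. Acadm, the medium-chain acyl-CoA dehydrogenase, measured 929.0 ± 80.1 and 763.1 ± 48.3 CPM (SD, n = 3 each). Etfa, Etfb and Cpt2 had log2 fold changes of -0.19 (SE 0.06), -0.17 (SE 0.07) and -0.16 (SE 0.07). Genes of gluconeogenesis and glycolysis fell by 0.06, with 15 of 19 negative (camera, adjusted p = 0.0265; adjusted p = 0.811 with an estimated correlation). That call was lost without nanoplastic 1 (adjusted p = 0.191), nanoplastic 3 (0.0507), vehicle 1 (0.138) or vehicle 2 (0.0974). Pgam1, Pgk1, Eno1 and Pfkp, which are glycolytic enzymes, had log2 fold changes of -0.21 (SE 0.06), -0.24 (SE 0.08), -0.18 (SE 0.07) and -0.29 (SE 0.11). Ppargc1a and Tfam, regulators of mitochondrial biogenesis, had log2 fold changes of 0.01 (SE 0.08) and -0.03 (SE 0.08). The list for mitochondrial biogenesis, dynamics and mitophagy had a median of -0.04 over 18 genes (adjusted p = 0.318), with Mfn2 at -0.15 (SE 0.06) and Tfb2m at -0.10 (SE 0.07).

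The list of NF-kB and inflammatory cytokines had 9 positive and 8 negative members and a median log2 fold change of 0.01 (camera, adjusted p = 0.929). Il1b, which encodes interleukin-1 beta, measured 2.17 ± 0.917 and 0.976 ± 0.211 CPM (SD, n = 3 each; log2 fold change -1.13, SE 0.35, edgeR adjusted p = 0.541). Cxcl1, a chemokine, measured 0.271 ± 0.292 and 0.699 ± 0.354 CPM (SD, n = 3 each; log2 fold change 1.44, SE 0.62). The groups overlapped, with vehicle 2 at 0.607 CPM and nanoplastic 2 and 3 at 0.584 and 0.416 CPM. Il6, Tnf and Ccl2 were below the count filter. Over the 3 libraries of a group, Il6 had 0 counts in vehicle and 4 in nanoplastic, Tnf had 18 and 15, and Ccl2 had 21 and 20. At these counts small differences in the cytokines were out of reach. Interferon and cGAS-STING genes had 12 positive and 13 negative members (adjusted p = 0.748), with Mx1 at 0.60 (SE 0.33) and Isg15 at -0.38 (SE 0.26).

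Senescence and SASP genes had 9 positive and 9 negative members and a median of -0.01 (camera, adjusted p = 0.7495). Cdkn1a, the cell cycle inhibitor p21, measured 1.22 ± 0.393 and 1.13 ± 0.148 CPM (SD, n = 3 each), and its 95% confidence interval in log2 fold change ran from -0.78 to 0.57. Cdkn2a, which encodes the inhibitor p16, had 1 count in all vehicle libraries and 0 in all nanoplastic libraries, both under the floor of 3 counts. Trp53, Lmnb1 and Tgfb1 had log2 fold changes of -0.19 (SE 0.16), 0.10 (SE 0.20) and -0.16 (SE 0.19), and Glb1, the lysosomal beta-galactosidase, of -0.16 (SE 0.07). The p53 target list had 7 positive and 12 negative members (adjusted p = 0.354), with Bbc3 at 0.80 (SE 0.29) and Aen at -0.24 (SE 0.10).

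Tubular injury genes had 9 positive and 7 negative members and a median of 0.01, with camera's direction lower (adjusted p = 0.749). Havcr1, the kidney injury molecule, measured 1.08 ± 0.534 and 1.03 ± 0.593 CPM (SD, n = 3 each), and its 95% confidence interval ran from -1.02 to 0.97. Lcn2, which encodes the injury marker lipocalin-2, had a log2 fold change of 0.16 (SE 0.38), Clu of -0.36 (SE 0.11) and Krt8 of 0.16 (SE 0.06). The injury score of nanoplastic 1 was 0.459, against -0.123 and -0.186 in nanoplastic 2 and 3 and -0.171 to 0.126 in vehicle. Without nanoplastic 1 the tubular injury and interferon lists were called lower with the preset correlation, at adjusted p values of 0.0215 and 0.0103, and an estimated correlation was not run without that library.

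**Figure D3:**
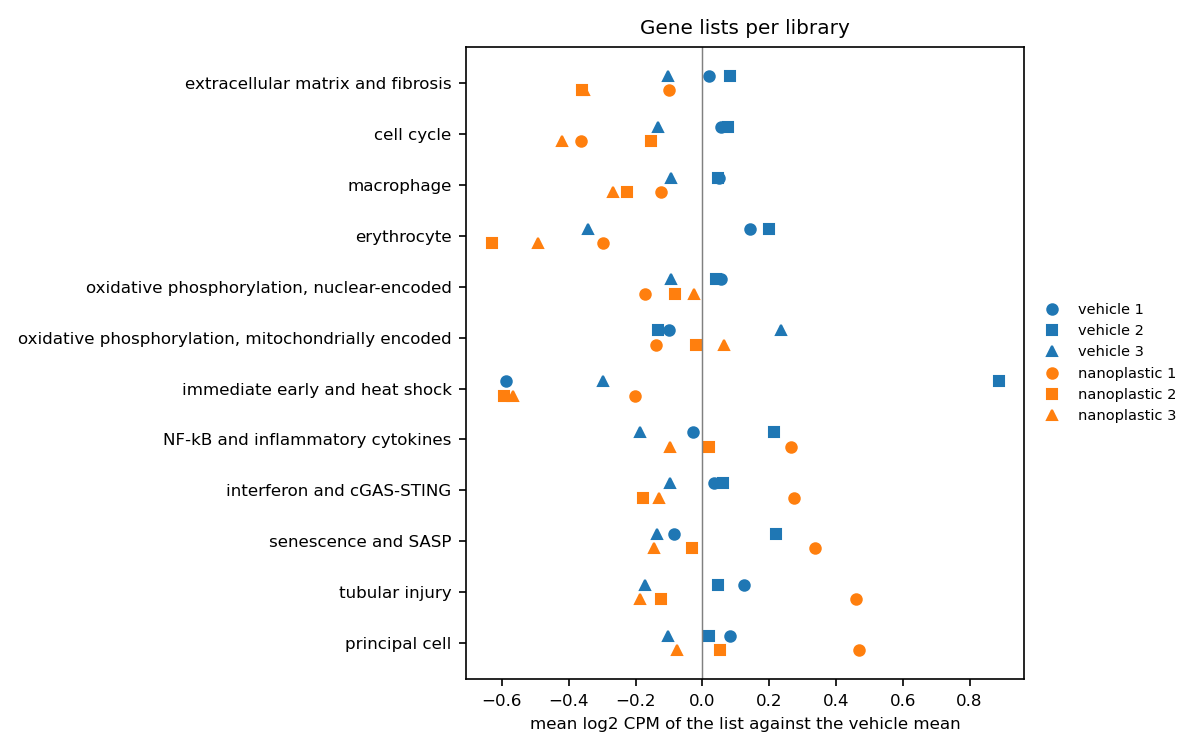
Mean log2 CPM of 12 gene lists in each library against the vehicle mean (x axis), with blue symbols for the 3 vehicle and orange symbols for the 3 nanoplastic libraries. In the cell cycle and macrophage lists all nanoplastic libraries lay below all vehicle libraries, and nanoplastic 1 stood at 0.459 in tubular injury and vehicle 2 at 0.887 in the immediate early and heat shock list.

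Adipocyte and urothelial transcripts were uneven among the libraries. Adipoq, the fat cell hormone adiponectin, had 130 counts in vehicle 3, 444 in nanoplastic 1 and at most 2 in each of the other 4 libraries. The adipocyte list had 1 gene above the count filter and was not tested. The urothelial gene Upk1b had 187 counts in nanoplastic 1 and 15 to 51 in the other libraries, and the urothelium list had an adjusted p of 0.559. Without vehicle 3 and nanoplastic 1, edgeR called 30 genes, 14 higher and 16 lower, in a comparison of 2 against 2 chosen after seeing the data. Col3a1, Azgp1, Hbb-bt, Cyp2a5, Dio1 and Hao2 were among them. The matrix list then had a median of -0.35 (adjusted p = 4.01e-12), and 11 lists were called lower, all with the preset correlation, since an estimated one, which called 0 lists in the 6 libraries, was not run in this comparison. Tubular injury and interferon genes (both at an adjusted p of 0.000428), the stress response (0.00588), urothelium (0.0101) and smooth muscle and mural cell markers (0.0431) were among them, and fatty acid oxidation (0.499) and gluconeogenesis and glycolysis (0.0705) were not.

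The immediate early and heat shock list fell by 0.35 in median log2 fold change, with 13 of 15 negative (camera, adjusted p = 0.0175; adjusted p = 0.811 with an estimated correlation). Vehicle 2 decided this value, and without it the adjusted p was 0.996. Without nanoplastic 2 or 3 it was 0.0709 or 0.0522. Jun, an early response transcription factor, measured 62.1 CPM in vehicle 2 and 16.9 CPM in vehicle 1, 26.04 CPM in vehicle 3 and 17.2 to 18.4 CPM in the nanoplastic libraries. Fos, Hsph1 and Hsp90aa1 had log2 fold changes of -2.08 (SE 0.92), -0.61 (SE 0.23) and -0.49 (SE 0.14). The value of Fos rested on 11.2 CPM in vehicle 2. It measured 1.325 CPM in vehicle 1, 1.02 CPM in vehicle 3 and 0.364 to 1.75 CPM in the nanoplastic libraries.

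None of the remaining metabolic and stress lists passed with camera's preset correlation. The camera adjusted p was 0.0683 for androgen-responsive renal genes, 0.0970 for the integrated and mitochondrial stress response, 0.169 for NRF2 and antioxidant genes, 0.569 for PPAR alpha and peroxisomal targets, 0.607 for cholesterol synthesis, 0.559 for lysosome and autophagy, 0.886 for tight junction and brush border transport and 0.455 for the circadian clock. Some were called lower by the preset correlation with 1 library left out: androgen-responsive genes without nanoplastic 3 (adjusted p = 0.0142) or vehicle 3 (0.0385), the stress response without nanoplastic 1 (0.0215) or vehicle 3 (0.0228), and NRF2 genes without nanoplastic 3 (0.0236). Odc1, the ornithine decarboxylase, measured 1608 ± 209 and 1129 ± 240.4 CPM (SD, n = 3 each), and Cyp7b1 had a log2 fold change of -0.33 (SE 0.10). Gclc, an enzyme of glutathione synthesis, measured 323.0 ± 74.3 and 221.5 ± 9.26 CPM (SD, n = 3 each), and Hmox1 had a log2 fold change of -0.34 (SE 0.10). Insig1, which restrains cholesterol synthesis, had a log2 fold change of 0.35 (SE 0.10). Hspd1 and Hspe1, mitochondrial chaperones, had values of -0.25 (SE 0.08) and -0.21 (SE 0.07). Ehhadh, Cyp4a31, Atg5 and Neu1 had values of -0.32 (SE 0.09), -0.27 (SE 0.11), -0.21 (SE 0.08) and 0.15 (SE 0.07). Abcb1b, a drug efflux transporter, measured 6.54 ± 0.775 and 10.1 ± 0.603 CPM (SD, n = 3 each), Slc6a19 had a log2 fold change of 0.38 (SE 0.14). The clock genes Ciart and Cry2 measured 2.45 and 11.2 CPM in nanoplastic against 1.01 and 8.62 CPM in vehicle.

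Markers of the nephron segments and other cells did not pass either. The adjusted p was 0.596 for proximal tubule, 0.318 for thick ascending limb, 0.749 for distal convoluted tubule, 0.499 for principal cell, 0.697 for intercalated cell, 0.849 for podocyte, 0.749 for endothelium, 0.555 for T cell and 0.429 for B and plasma cell. Umod, which encodes uromodulin of the thick ascending limb, measured 3904 ± 468 and 3116 ± 247 CPM (SD, n = 3 each). Slc5a12 and Slc22a30, proximal tubule transporters, had log2 fold changes of 0.19 (SE 0.07) and -0.27 (SE 0.09), and Aqp6 of intercalated cells had 0.58 (SE 0.14). Aqp2, the water channel of principal cells, had a log2 fold change of 0.65 (SE 0.34) that rested on 148.7 CPM in nanoplastic 1 and was -0.02 without it. Adrenal, neutrophil and skeletal muscle lists had fewer than 3 measured genes and were not tested.

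The groups overlapped on the first principal component of the overall profile and not on the second. Pearson correlations of log2 CPM ran from 0.984 to 0.989 between groups, up to 0.988 among vehicle and from 0.982 to 0.988 among nanoplastic libraries. The first principal component held 27.9% of the variance and set nanoplastic 1 apart, at -40.9 against 0.2 to 22.0 in the other 5 libraries. The second held 23.4%, with vehicle 2 apart at -36.5, vehicle 1 and 3 at -3.2 and -0.4, and the nanoplastic libraries at 6.1 to 19.2. The share of counts from mitochondrial ribosomal RNA was 0.858% in nanoplastic 3 and 1.35% to 1.72% in the other libraries.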

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

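The alternatives were set before the data were examined, except the legacy edgeR test and the fit without vehicle 3 and nanoplastic 1, which were chosen after seeing the data. Where a value below differs from the main one, the cause was not tested unless stated. Of 80 genes given with a value from the main test, 72 kept their direction in every alternative run, and all 8 lists called with the preset correlation kept theirs. The 0 genes called by edgeR became 56 with DESeq2 (test and gene filter changed together), 3 with robust dispersion (Azgp1, Col1a1 and Col3a1, each at an adjusted p of 0.0489), 1 with limma-trend on log2(TPM + 1) (Gm11522, named after its value was seen), 30 without vehicle 3 and nanoplastic 1, and between 0 and 10 with 1 library left out. In the other alternatives, the legacy test included, the count was 0. The 8 lists called became 0 with an estimated correlation, 0 with fry in 1 direction, 4 with fry's mixed test, which has no direction, and between 5 and 10 with 1 library left out, the 5 being without vehicle 2. The nuclear oxidative phosphorylation list had adjusted p values of 0.811 with an estimated correlation, 0.813 with fry in 1 direction and 0.4996 with its mixed test. Library size alone moved the median log2 fold change by 0.0449, and RLE scaling by -0.003. The replicate numbers, which both groups share, are not said to pair the mice. Deviations of libraries with the same number correlated at 0.044, -0.023 and 0.103, and not every library correlated best with its own number. Such weak correlations do not show a pairing and cannot exclude one. With the replicate block 0 genes and 6 lists were called. Depth limits rare transcripts such as Il6 and Cdkn2a, which had at most 4 counts in a group.

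The 8 genes that turned direction had main log2 fold changes from -0.16 to 0.16, except Aqp2 at 0.65. With library size alone Havcr1 was at 0.0174 and Tfam at 0.0150. On log2(TPM + 1) and log2(TPM + 0.1), Lmnb1 was at -0.0264 and -0.0523, Ppargc1a at -0.0051 and -0.0052, Tfam at 0.0320 and 0.0329, and Tgfb1 at 0.0199 and 0.0202. Without vehicle 3 and nanoplastic 1, Aqp2 was at -0.161, Havcr1 at 0.0697, Lcn2 at -0.450 and Lmnb1 at -0.0653. With 1 library left out, log2 fold changes ran from -0.0204 to 0.942 for Aqp2, from -0.335 to 0.141 for Cdkn1a, from -0.636 to 0.435 for Havcr1, from -0.230 to 0.452 for Lcn2, from -0.0375 to 0.0787 for Ppargc1a and from -0.0828 to 0.0228 for Tfam.

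Without vehicle 3 and nanoplastic 1, interferon and tubular injury genes were called lower, both at an adjusted p of 0.000428, and so were the integrated and mitochondrial stress response at 0.00588 and smooth muscle and mural cell markers at 0.0431, while urothelial markers turned lower at 0.0101. Fatty acid oxidation (0.499) and gluconeogenesis and glycolysis (0.0705) were no longer called, which left 11 lists. Other lists that turned direction there did not pass, with adjusted p values of 0.368 for distal convoluted tubule, 0.0795 for NF-kB and inflammatory cytokines, 0.555 for mitochondrially encoded subunits, 0.172 for PPAR alpha targets, 0.616 for principal cell and 0.555 for proximal tubule. With the filter of 1 CPM, NF-kB and inflammatory cytokines turned lower at 0.542. With 1 library left out, lists that turned direction had adjusted p values from 0.0509 to 0.842 for B and plasma cell, 0.358 to 0.950 for NF-kB, 0.169 to 0.860 for PPAR alpha targets, 0.126 to 0.944 for T cell, 0.104 to 0.903 for distal convoluted tubule, 0.480 to 0.913 for endothelium, 0.0511 to 0.903 for intercalated cell, 0.0103 to 0.931 for interferon, 0.247 to 0.842 for lysosome, 0.391 to 0.943 for podocyte, 0.261 to 0.714 for proximal tubule, 0.337 to 0.931 for senescence, 0.480 to 0.949 for tight junction and transport, 0.0215 to 0.913 for tubular injury and 0.246 to 0.935 for urothelium.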

Other observations

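The tests of chance, of tissue carried along and of the collagen family were chosen after the result was seen. The tests of fibroblast markers, sequence content and depth were not. The glucocorticoid test was prompted by 4 genes with positive log2 fold changes and was set before the values of its 14 other genes were seen. In the count-based test of DESeq2, which called 56 genes, further matrix genes were lower: Col5a2 at -0.59, Col15a1 at -0.52, Col14a1 at -0.37 and the collagen-modifying enzyme Plod2 at -0.41 in log2 fold change. DESeq2 also called lower Lpl, which encodes lipoprotein lipase, at -0.51, the fatty acid transporter Cd36 at -0.34, the bile acid receptor Nr1h4 at -0.51 and the organic anion transporter Slc22a7 at -0.69. The iron exporter Slc40a1 was called lower at -0.32 beside the transferrin receptor Tfrc at -0.41. Called higher were Pigr, the receptor that carries polymeric immunoglobulin, at 0.44, Car9, a carbonic anhydrase, at 0.78, and Klf15 at 0.38. These genes were chosen after their values were seen, and edgeR gave each an adjusted p above 0.05.

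Whether the fall extends to collagens in general was tested on the 30 measured collagen genes outside the matrix list, some of which had been seen before. Of these 53.3%, or 16, had a negative log2 fold change (exact binomial two-sided p = 0.856), so a fall of the whole family was not shown. At an unadjusted p under 0.05, 8 of the 30 were lower and 1 was higher. The lower values were in collagens such as Col5a2, Col15a1, Col14a1 and Col6a3, while Col13a1 was at 0.90 (SE 0.35).

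The lower matrix list was weighed against technical explanations. Sequence content is argued against, since 10000 lists matched on GC content, length and expression had a median of 0.019, against -0.25. Of these lists 0% were as low, but their genes were drawn independently. That share therefore does not measure how unusual the list is. Thinning all libraries to the smallest total left a median of -0.252. Such thinning lowers all genes of a library in proportion, so the median could hardly move and depth is not excluded. Tissue in vehicle 3 and nanoplastic 1 is argued against, since without both the median was -0.346. A smaller share of fibroblasts stays open: 11 fibroblast markers that are not collagens had a median of -0.194, 8 fibroblast collagens had -0.39, and the exact permutation p was 0.105, so fewer fibroblasts may account for part of it and cannot be told apart from lower collagen expression or from nanoplastic itself. The real split gave an absolute median of 0.254 and the highest of the other 9 splits gave 0.216, and with 10 splits, of which 1 reached the real value, a share under 0.05 is out of reach.

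The nuclear oxidative phosphorylation list is made of short transcripts, and matched lists had a median of -0.05 against -0.09 for the list. Of 10000 matched lists 0.01% were as low. Their genes were drawn independently, while the genes of the real list had an estimated correlation of 0.685. The share therefore does not measure how unusual the list is, and short transcripts as the cause stay open. Among the 10 splits, 3 gave an absolute median as large as the real 0.0929, and the highest other was 0.136. With 10 splits a share under 0.05 is out of reach. Tests against the variation between mice did not pass, at adjusted p values of 0.811 with an estimated correlation and 0.813 with fry, so an effect of nanoplastic stays open.

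The adipocyte transcripts in vehicle 3 and nanoplastic 1 may come from fat carried along with the kidney. All 6 adipocyte markers (Adipoq, Cfd, Cidec, Lep, Plin1 and Retn) stood above the other 4 libraries in both, with ratios of nanoplastic 1 to vehicle 3 between 1.64 and 4.98. These 6 leave out Car3 and Ucp1 of the fixed list. Ucp1 had 10 counts in vehicle 3 and 106 in nanoplastic 1, a larger ratio than that of any of the 6. The most abundant, Cfd, had 301 counts in vehicle 3 and 1511 in nanoplastic 1. Exposure as the cause in both is argued against by values seen before that test was written. Summed over the 6 markers, vehicle 3, which was not exposed, had 27.84 CPM, and nanoplastic 2 and 3 had 0.13 and 0.10 CPM, so the lowest nanoplastic minus the highest vehicle library was -27.74 CPM. Whether exposure adds to the level in nanoplastic 1 stays open.

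Of single genes, edgeR called 0 in the real split and at most 2 in the others. All 10 splits reach a count of 0 whatever the data, so this comparison decides nothing. At an unadjusted p under 0.05 the real split gave 1342 genes and the highest other 1512, and 2 of 10 splits gave as many as the real one. Of lists, 8 were called in the real split and 22 in the highest other, which set vehicle 1, vehicle 2 and nanoplastic 1 against the rest, and 3 of 10 splits gave as many as the real one. With 10 splits a share under 0.05 is out of reach. With an estimated correlation 0 lists were called in each of the 10 splits, the real one included, so that test cannot tell the splits apart. Whether the 22 lists reflect a structure of the samples other than the groups stays open.

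Because Klf15, Irs2, Tsc22d3 and Arrdc2 had positive log2 fold changes (0.384, 0.962, 0.372 and 0.632) that edgeR did not call (adjusted p of 0.311 to 0.319), a shared glucocorticoid or fasting response was set up as a hypothesis and tested on 14 other responsive genes. Their median log2 fold change was 0.156, and 10 of 14 were positive. A bootstrap interval of the median ran from 0.001 to 0.233. It resampled the 14 genes and not the mice, so it does not measure the spread between mice. Camera with an estimated correlation did not call the set, Fkbp5 was at -0.32 (SE 0.19) and Bcl6 at -1.56 (SE 0.49), so these genes neither show nor exclude such a response.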
